A study of Danio rerio with 6 samples.

How the data were processed

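Total RNA was taken from zebrafish embryos at the sphere stage, extracted with Trizol and labelled with Cy3 by the array maker, per the labels' protocols. Groups were taken from the sample titles: 3 arrays of embryos injected with a control morpholino and 3 of embryos injected with nanog-like MO1. The labels describe separate cultures, so the spread between arrays is taken as the spread between cultures.

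For each array the authors deposited 1 intensity per target, the mean brightness of the target's perfect-match probes on a linear scale, with the number of probes, the number kept after filtering and their coefficient of variation, per the file headers. The filter is not given in the sources used here, and the mismatch columns were 0 throughout. These intensities had not been normalized between arrays: their medians ran from 408 to 529 and their lowest values from 77 to 119. The authors also deposited a value table of the same arrays, made with RMA per the submitters' processing notes, with the version not given in the sources used here. Its values are intensities on a linear scale. Its column medians lay between 179.39 and 200.32, and how the authors scaled or centred its columns stays unknown beyond the name RMA. Its log2 fold changes correlated with those from the per-array intensities at 0.889 across targets, which are not independent replicates. No detection call per target was in the columns used here.

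The plan, fixed before the data were examined, had expected RMA values per array, or probe values to be summarised by median polish. The per-array intensities turned out to be raw means per target, so background was corrected with normexp (offset 50), arrays were quantile normalized, and values were taken to log2. Median polish could not be applied, since probe values were not used here. The RMA table served as an alternative. The lowest normalized value was 5.66, the 25th percentile of target means 6.74 and the median 8.66. The offset compresses differences among dim targets, so their folds are understated, and quantile normalization assumes that most targets do not shift.

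Targets were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, 2-sided, group as the only term), with Benjamini-Hochberg adjustment over all 38489 targets and a threshold of 0.05 on the adjusted p. Fold changes are morpholino over control.

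Targets were named in turn by RefSeq transcript accession (2663 targets), a current symbol in the array design (4468), an Entrez gene number (1975), an older symbol that is a synonym of exactly 1 gene (5746), an accession in the design's name (19) or description (7), or a map marker that the design places on the target's own chromosome (1081). Names were looked up in a RefSeq gene table of assembly GRCz12tu, from which no coordinate was used. Of 1363 targets named in both ways, the map marker gave the same gene for 95.7%. The targets of tbx16, vox, gata6, id1, ccnd1, tbxta, sox9a, dld, ndr2, grip2a, ppiaa and gapdh were named by map marker. A usable symbol was found for 14342 of 38489 targets, giving 10399 genes, of which 2660 had more than 1 target. A further 6386 targets kept a clone or project name, 14764 had none, and 1380 reverse-strand targets were not named. A gene with several targets was represented by the one with the highest mean over the 6 arrays. Coordinates are those of the array design, on assembly Zv7, whose scaffold names the design uses. The gene sox32 was not analysed here, since no target carried its name.

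The genes named in the text follow a rule fixed before the data were examined. They are nanog, and mxtx2, ndr1, ndr2, tbxta and pou5f3 whatever their values. Of the genes with an adjusted p under 0.05, an absolute log2 fold change of at least 1 and groups that did not overlap, the 12 with the largest fall and the 12 with the largest rise are named. Of each list, the 4 members with the smallest adjusted p that passed are named, or where none passed the 2 with the largest absolute log2 fold change. Of 16 lists fixed at the same time and partly overlapping, 15 are given, since 1 list and 2 genes that the rule names are not reported here. Counts of lists and of named genes that passed cover only those given. They cover Nodal signalling, endoderm, yolk syncytial layer, mesoderm and margin, dorsal organizer, ventral and BMP genes, enveloping layer, early zygotic genes, oocyte and maternal genes, germ plasm, pluripotency factors, neuroectoderm, cell cycle, stress and interferon genes, and reference genes. Each was tested with camera at a preset correlation of 0.01 on 1 target per gene, adjusted over all 16 lists, with an estimated correlation and fry as alternatives. The single nanog level was also tested with a 2-sided exact permutation test. Intervals of 95% use the fit's SE and 4 residual degrees of freedom.

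Data were simulated from the real means and spreads of this comparison over 38489 targets. In them 100 targets were changed by 1 and 100 by 2 on the log2 scale, all drawn from targets brighter than the median. The procedure recovered 21% and 83% of them, with 2 false calls among 106, and made 0 calls where nothing was changed. Recovery among dimmer targets was not simulated. Noise was drawn independently for each target, so a batch difference shared by many targets was not simulated either. Rank correlations of raw intensities between arrays were 0.978 to 0.983 within groups and 0.969 to 0.981 between groups, and at most 1.27% of values were equal on any 2 arrays, so no 2 arrays held the same values.

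Alternatives tried were quantile normalization with no background correction, centring on the reference genes, the RMA table, leaving out targets below the 25th percentile, the replicate number as a block, the array number range as a batch term, limma with a trended and robust prior, array weights, an ordinary test per target, 1 target per gene, the mean over a gene's targets, and leaving out each array.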

Results

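Total RNA of zebrafish embryos at the sphere stage, a blastula stage soon after transcription from the embryo's own genome has begun, was hybridised to 1-colour expression arrays. Embryos in one group had received a control morpholino and those in the other nanog-like MO1. Morpholinos are antisense oligonucleotides that block the translation or splicing of a chosen transcript. Here the target was nanog-like, now named nanog, a homeobox transcription factor that the mother supplies to the egg. Each group had 3 arrays, which the labels call biological replicates from separate cultures. The labels give a normal phenotype for the control embryos and a defect in gastrulation for the morpholino embryos. Each array reported 38489 targets from 387190 probes, of which 384758 to 385461 were kept per array. Median raw intensities lay between 408 and 529. The number of arrays limits the precision. The numbers in the array labels fall into ranges, and 1 range held all 3 control arrays and morpholino replicate 3, so that comparisons inside it rest on 1 morpholino array.

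The level of nanog itself came first. The nanog target NM_001098392, placed on build Zv7 chromosome 24 from 19808748 to 19813828, was among the brightest on the arrays, with 99.9% of targets dimmer. Its normalized intensity was 14.91 ± 0.06 on the log2 scale (SD, n = 3) in control embryos and 14.89 ± 0.06 (SD, n = 3) in morpholino embryos. The difference of -0.017 (SE 0.097) had a 95% interval of -0.286 to 0.252, and a 2-sided exact permutation test gave p = 0.7, where the smallest p that 3 against 3 arrays allow is 0.1. A morpholino that blocks translation need not lower its transcript, and the labels do not say how this one acts, so the level is no check of the knockdown. The level of pou5f3, a maternal POU factor, was 14.56 ± 0.11 in control and 14.38 ± 0.03 in morpholino embryos (SD, n = 3), with adjusted p = 0.636. Log2 fold changes of 2 Nodal ligand genes were -0.38 (SE 0.20, adjusted p = 0.594) for ndr1 and -0.33 (SE 0.15, adjusted p = 0.553) for ndr2, both fitted with limma.

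The comparison of the groups asked which transcripts differed at the sphere stage after injection of the morpholino against nanog. Several transcription factor genes of the early embryo were far lower in morpholino embryos. The level of sox3, a SoxB1 factor of early ectoderm, fell 17.8-fold, from 13.74 ± 0.12 to 9.59 ± 0.38 (log2, SD, n = 3), and that of tbx16, a T-box factor of mesoderm, fell 17.7-fold, from 12.66 ± 0.13 to 8.52 ± 0.40 (log2, SD, n = 3). The hairy-related repressor gene her5 fell 16.9-fold, the zinc finger gene blf 12.3-fold and the ventral homeobox gene vox 8.27-fold. In the other direction her3, another hairy-related repressor gene, rose 10.5-fold, from 9.32 ± 0.27 to 12.72 ± 0.48 (log2, SD, n = 3), and sox9a rose 6.56-fold.

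**Figure D1:**
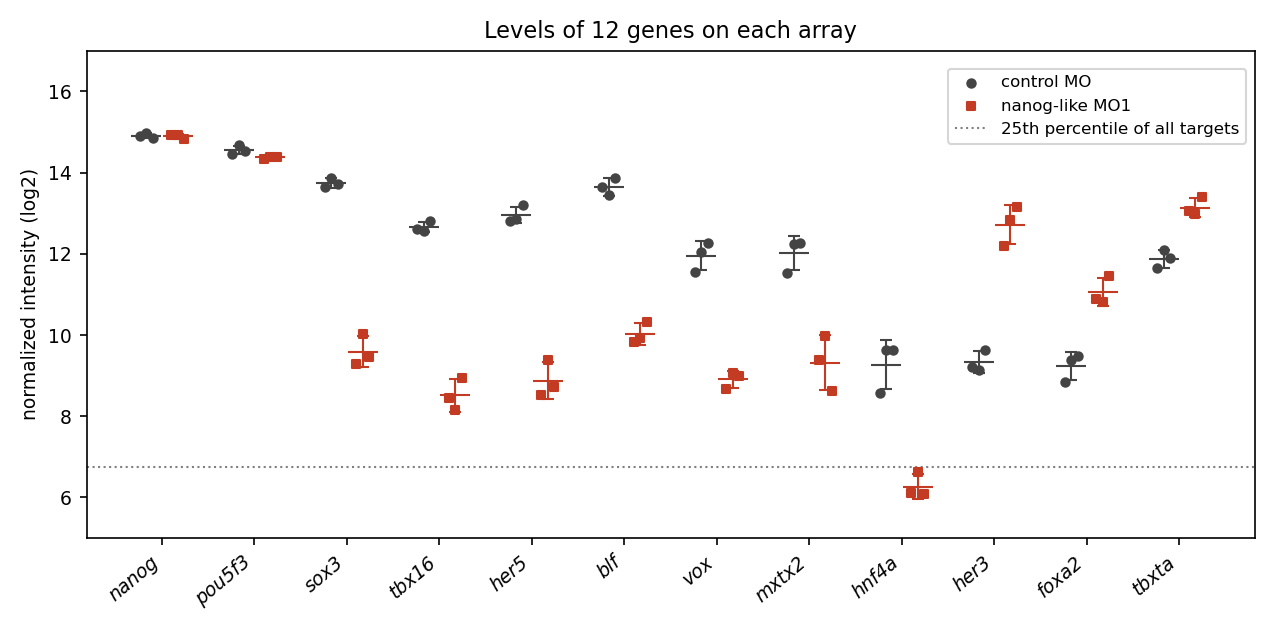
Normalized log2 intensity of 12 genes on the 3 control arrays (circles) and the 3 morpholino arrays (squares), where horizontal dashes are group means, bars are 1 SD and the dotted line is the 25th percentile of all target means (6.74). The nanog and pou5f3 points lie close together, while sox3, tbx16, her5, blf, vox, mxtx2 and hnf4a are lower and her3, foxa2 and tbxta higher on all 3 morpholino arrays.

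Over all targets, 99 were higher and 150 lower in morpholino embryos at an adjusted p under 0.05 (limma), and 89 and 138 of them differed by at least 2-fold. At an unadjusted p under 0.05 the same limma fit gave 2039 higher and 1935 lower. A share of 0.05 of all targets would pass that threshold with no difference. The arrays of the groups did not overlap on 15.3% of all targets, against 10% by chance. Leaving out 1 array at a time left 34 to 67 higher and 59 to 120 lower, the fewest without control replicate 3. With the array number range as a batch term, which leaves 1 morpholino array to carry the difference, limma called 0 targets, against 1904 higher and 1676 lower at an unadjusted p under 0.05. On all 249 called targets the morpholino arrays lay to the same side of all control arrays, so no sign could change there. Log2 fold changes of morpholino replicate 3 against the control mean were -4.28 for sox3, -3.72 for tbx16, -4.24 for her5 and 3.82 for her3. That array also entered the main calls, so these values are no separate support. The share of higher against lower calls depended on the scaling. Centring each array on the reference genes moved the median log2 fold change of all targets from -0.012 to 0.172, with 399 higher and 141 lower.

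The 12 named genes with the largest falls were cdk5r1a, sox3, tbx16, her5, rnd1b, irx1b, blf, morc3b, stmn2a, arl4ab, vox and hnf4a. Their log2 fold changes ran from -4.35 (SE 0.22, adjusted p = 0.00164) for cdk5r1a, which encodes an activator of the kinase Cdk5, to -3.00 (SE 0.32, adjusted p = 0.0157) for hnf4a, a nuclear receptor gene. The gene rnd1b fell 14.6-fold and irx1b, which encodes an Iroquois factor, fell 12.6-fold. For cdk5r1a, stmn2a, hnf4a and gata6 the morpholino level lay below the 25th percentile of target means, as did the control level of g6pc1b, and this scale understates the change of such dim targets. In the authors' value table the log2 fold changes were -5.82 for cdk5r1a, -5.68 for stmn2a, -3.63 for hnf4a and -3.71 for gata6, and that of g6pc1b was 3.09 there against 1.64 here. The 12 with the largest rises were her3, sox9a, carmil2, fzd10, klf15, arrdc3a, dld, foxa2, serpinh1b, g6pc1b, fzd9b and cdx4. Log2 fold changes ran from 3.39 (SE 0.27, adjusted p = 0.00519) for her3 to 1.49 (SE 0.19, adjusted p = 0.033) for cdx4, a caudal homeobox gene of posterior tissue. The Wnt receptor genes fzd10 and fzd9b rose 4.35-fold and 3.01-fold, and dld, a Notch ligand gene, rose 3.61-fold. On Zv7, sox3 lies on chromosome 14 from 36979548 to 36980450, tbx16 on chromosome 8 from 46498994 to 46516304, her5 on chromosome 14 from 19991484 to 19993160 and her3 on chromosome 8 from 42919487 to 42920708. Whether the probes lie in coding sequence or UTR was not analysed here. Of the 35 named genes that passed the test, 13 passed it without each array in turn: stmn2a, tbx16, rnd1b, cdk5r1a, sox3, blf, morc3b, her5, vox, osr1, her3, arl4ab and irx1b, the last with a highest adjusted p that rounds to 0.05. The other 22, among them hnf4a, mxtx2, sox9a, foxa2, cdx4, tbxta, lft1 and bbc3, were lost without at least 1 array.

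Early zygotic genes, those first transcribed from the embryo's genome, had a list median of -0.68 and were lower by the list test (camera, preset correlation of 0.01, adjusted p = 8.1e-11), with adjusted p = 0.133 with an estimated correlation. Of 27 measured members 11 fell, 1 rose and 15 did not pass the test, with 12 lower and 3 higher when adjusted over the list alone. The members with the smallest adjusted p were sox3, tbx16, blf and vox, and the member that rose was her3. Of 18 pluripotency factors 1 fell (sox3), 0 rose and 17 did not pass, though for 1 of the 17 a further target of the gene passed, lower. Adjusted over the list alone, 5 were lower and 1 higher. The list median was -0.14, with adjusted p = 0.00603 by camera, adjusted p = 0.412 with an estimated correlation and adjusted p = 0.057 without morpholino replicate 3. With the arrays centred on the reference genes, which moved all targets up, the median was 0.049 and the test stayed down (adjusted p = 0.000341). Of 20 neuroectoderm genes 4 fell, 1 rose and 15 did not pass, with 6 lower and 2 higher adjusted over the list alone. Those that fell included irx1b and cyp26a1, which encodes an enzyme that breaks down retinoic acid and was 5.76-fold lower, and her3 again was the gene that rose. The median was -0.23, with adjusted p = 0.00263 by camera and adjusted p = 0.273 with an estimated correlation. With the arrays centred on the reference genes it was -0.00045, against 0.172 over all targets, and the test stayed down (adjusted p = 8.12e-06).

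Genes of the yolk syncytial layer, the nucleated layer at the surface of the yolk, had a list median of -0.57, lower by camera (adjusted p = 0.000164), with adjusted p = 0.173 with an estimated correlation. Of 11 measured members 3 fell, 0 rose and 8 did not pass, with 4 lower and 0 higher adjusted over the list alone. The homeobox gene mxtx2 (Zv7 chromosome 12, 20912908 to 20914449) fell 6.45-fold, from 12.01 ± 0.42 to 9.32 ± 0.68 (log2, SD, n = 3, adjusted p = 0.0444), hnf4a fell 8.02-fold and gata6, a zinc finger factor gene, fell 5.18-fold, both folds understated on this scale. Of 14 ventral and BMP pathway genes 4 fell, 0 rose and 10 did not pass, with 6 lower and 0 higher adjusted over the list alone. These were vox, bambia, a BMP pseudoreceptor gene (4.15-fold), gata3 (3.64-fold) and id1, a target gene of BMP signalling (2.67-fold). The median was -0.25, with adjusted p = 9.17e-05 by camera and adjusted p = 0.133 with an estimated correlation. With the arrays centred on the reference genes the ventral and BMP median was -0.017 and that of the yolk syncytial layer -0.30, against 0.172 over all targets. Without background correction mxtx2 and gata3 did not pass (limma, adjusted p = 0.0626 and 0.0655).

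Members of the mesoderm and endoderm lists passed in both directions, while the organizer and Nodal signalling lists each had 1 member that passed, higher. Of 25 mesoderm and margin genes 3 fell (tbx16, her5 and osr1, the last 4.45-fold), 2 rose and 20 did not pass, with 5 lower and 5 higher adjusted over the list alone. Those that rose were cdx4, 2.81-fold, and tbxta, the zebrafish Brachyury gene, 2.40-fold, from 11.88 ± 0.23 to 13.14 ± 0.23 (log2, SD, n = 3, adjusted p = 0.0401). In the authors' value table tbxta had adjusted p = 0.0512, and the log2 fold change of osr1 was -3.04 there against -2.15 here. Of 11 endoderm genes gata6 fell, foxa2 rose and 9 did not pass, with 3 lower and 1 higher adjusted over the list alone. The forkhead factor gene foxa2 was 3.52-fold higher and was also the single member of 19 dorsal organizer genes that passed, 18 not passing, with 3 lower and 5 higher adjusted over the list alone. Of 12 Nodal signalling genes 1 rose and 11 did not pass, with 0 lower and 2 higher adjusted over the list alone. The gene that rose was lft1, a Nodal antagonist gene, at 2.53-fold. Without background correction foxa2, tbxta and lft1 did not pass (adjusted p = 0.0563, 0.0517 and 0.0592). None of these 4 lists passed the camera test, with adjusted p = 0.811 for mesoderm, 0.396 for endoderm, 0.811 for the organizer and 0.835 for Nodal signalling. The endoderm list had adjusted p = 0.0281, down, by camera with the arrays centred on the reference genes, though its median there was 0.11. With an estimated correlation on the main values it had adjusted p = 0.626. For mesoderm the median (0.03) and the test (up) had the opposite sign to the mean (-0.24), and for Nodal signalling and the organizer the medians (-0.056 and -0.057) had the opposite sign to the means (0.15 and 0.07) and tests.

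Genes of the stress and interferon response had a list median of 0.23, higher by camera (adjusted p = 0.000219), with adjusted p = 0.133 with an estimated correlation. Of 17 measured members 0 rose, 0 fell and 17 did not pass, with 4 higher and 0 lower adjusted over the list alone. The largest log2 fold changes were 1.16 (SE 0.22, adjusted p = 0.121) for stat1a and 1.08 (SE 0.24, adjusted p = 0.177) for ddit3, and with the arrays centred on the reference genes both passed, at adjusted p = 0.0129 and 0.0251. Without control replicate 1 stat1a passed too (adjusted p = 0.0393). Outside this list, the gene bbc3, which encodes a protein that promotes cell death, rose 2.34-fold (adjusted p = 0.0259). Of 21 cell cycle genes ccnd1, the cyclin D1 gene, fell 2.15-fold, 20 did not pass, and adjusted over the list alone the counts were 1 lower and 0 higher. The list test gave adjusted p = 0.31.

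Lists of maternal, germ plasm, enveloping layer and reference genes had medians near 0 and no member that passed in the test of all targets. The medians were -0.014 over 22 oocyte and maternal genes, -0.021 over 11 germ plasm genes, 0.018 over 20 enveloping layer genes and -0.036 over 13 reference genes, with adjusted p by camera of 0.965, 0.554, 0.31 and 0.31. Adjusted over the list alone, 1 germ plasm gene and 1 enveloping layer gene were higher and 0 members of these 4 lists were lower. For germ plasm the median had the opposite sign to the mean (0.08) and the test. The members with the largest log2 fold changes were org (0.46, SE 0.25) and zar1 (-0.33, SE 0.16) among maternal genes, tdrd6a (0.96, SE 0.20) and grip2a (-0.15, SE 0.14) among germ plasm genes, evpla (2.16, SE 0.43) and pkp3a (0.75, SE 0.31) in the enveloping layer, and ppiaa (-0.34, SE 0.11) and gapdh (-0.23, SE 0.13) among reference genes. With the arrays centred on the reference genes tdrd6a and evpla passed (adjusted p = 0.023 and 0.0215), and evpla also passed in the authors' value table (adjusted p = 0.0452). A further target of evpla went the other way. The enveloping layer list passed the camera test, higher, without control replicate 2 (adjusted p = 0.0053) and without morpholino replicate 2 (adjusted p = 0.0465). Both are at the preset correlation. On all arrays the estimated correlation of this list was 0.47, and camera with it gave adjusted p = 0.894.

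**Figure D2:**
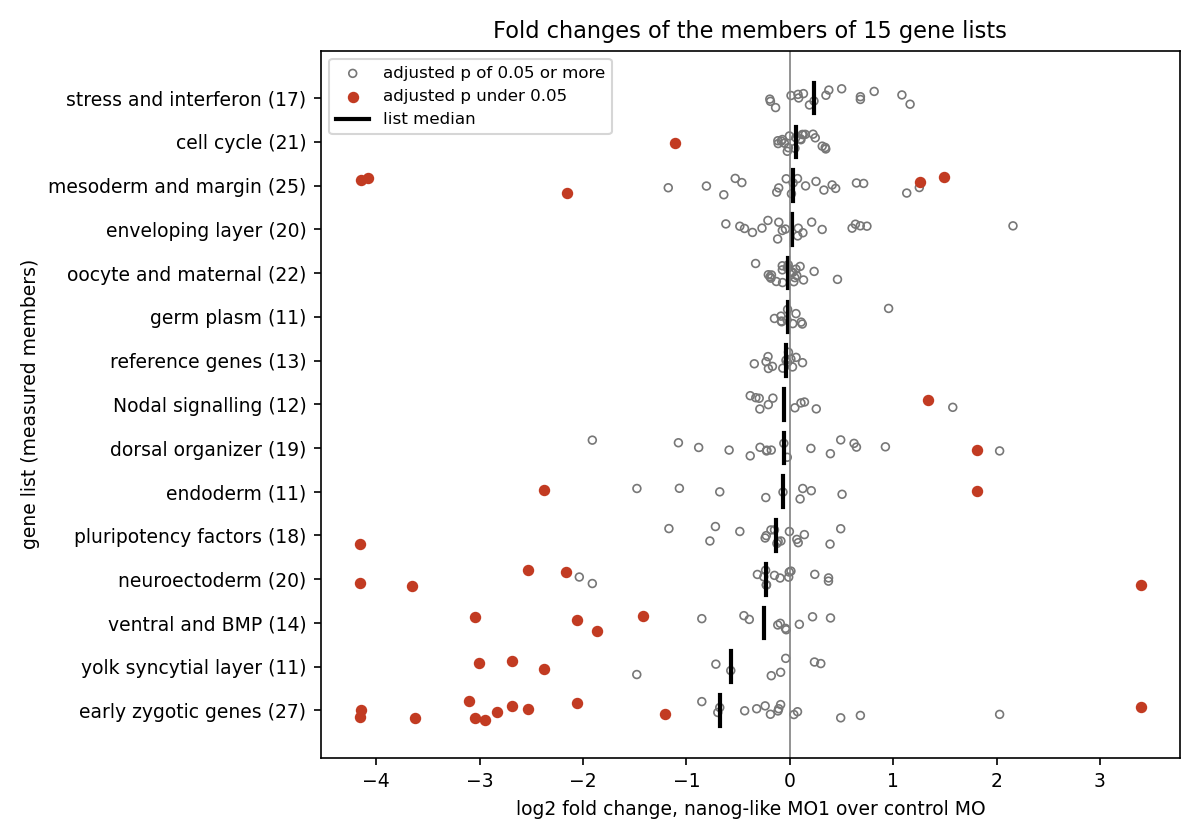
Log2 fold change, morpholino over control, of each measured member of the 15 gene lists, ordered by list median (black bars), with the number of measured members after each name and filled points for an adjusted p under 0.05 over all targets. Early zygotic genes have the lowest median (-0.68) and stress and interferon genes the highest (0.23), and 11 of the 27 early zygotic genes are filled points to the left of 0.

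Inside the array number range that holds both groups, with 3 control arrays and 1 morpholino array, the 6 of the 15 lists given here that passed the camera test had medians of the same sign. These were -0.50 for early zygotic genes, -0.42 for the yolk syncytial layer, -0.34 for ventral and BMP genes, -0.27 for pluripotency factors, -0.22 for neuroectoderm and 0.40 for stress and interferon genes. With the range as a batch term their adjusted p was 5.01e-06, 0.0162, 0.0141, 0.00307, 0.0363 and 0.00307 in the same order. None passed there with an estimated correlation, at adjusted p = 0.654, and 0.659 for neuroectoderm. The enveloping layer list, with a median of 0.42 inside the range, had adjusted p = 0.00403 there and adjusted p = 0.659 with an estimated correlation. All of these p rest on 1 morpholino array. That array and the 3 control arrays also entered the test that picked the 6 lists, so their shared signs are no separate support.

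A large part of the higher targets came from 2 stretches of the genome, singled out after their values were seen. On Zv7 chromosome 19 from 12039938 to 12612658, 17 of 23 targets rose, by 1.59 to 2.43 on the log2 scale, and the array design describes all 17 as similar to the pim oncogene family, which encodes serine/threonine kinases. Of the 66 targets anywhere on the array named or described as pim family, these 17 were higher, 0 lower and 49 did not pass. On Zv7 chromosome 7 from 33737721 to 34229435, 19 of 27 targets rose, by 1.78 to 3.21, and none of these 19 had a gene symbol beyond provisional locus names. Most other targets inside the spans lay near 0, between -0.13 and 0.23 for 7 targets on chromosome 7 and between -0.09 and 0.36 for 5 targets on chromosome 19. Most of these 7 on chromosome 7 were dim in both groups, with mean levels from 5.98 to 6.75 against a 25th percentile of 6.74. Folds near 0 at such levels do not show that these transcripts were unchanged. A further target on each did not pass, with log2 fold changes of 2.43 (SE 0.39, adjusted p = 0.0755) on chromosome 7 and 2.86 (SE 0.91, adjusted p = 0.345) on chromosome 19. Probe sequences were not compared here, and probes of similar targets may report each other's transcripts, so the number of transcripts that rose is uncertain. With the array number range as a batch term 0 targets of either span passed. Without control replicate 3 the number that rose was 17 on chromosome 7 and 8 on chromosome 19, and on chromosome 19 it was 11 without control replicate 2 or without morpholino replicate 3. With called targets within 1 Mb of each other counted once, a count added after the data were seen, there were 52 higher and 103 lower loci, besides 4 higher and 3 lower targets with no position.

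**Figure D3:**
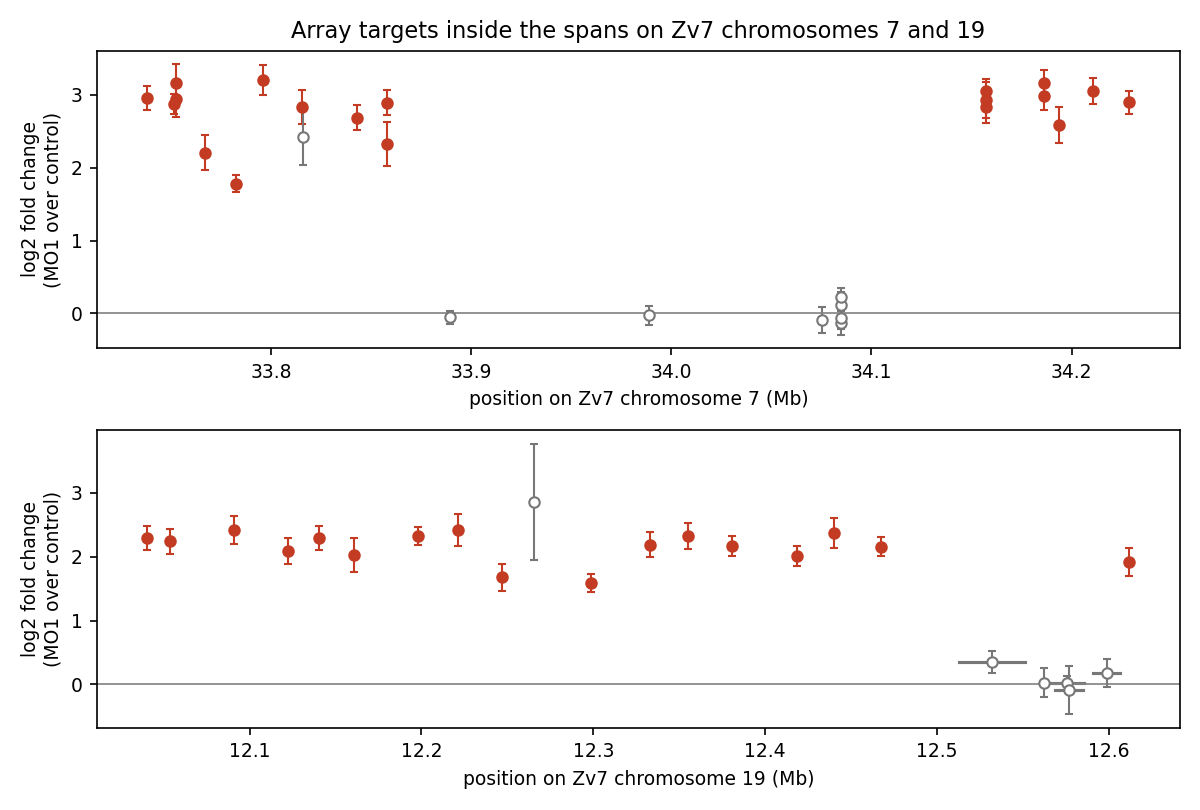
Log2 fold change, morpholino over control, of every target inside the spans on Zv7 chromosomes 7 and 19, against position in Mb, with vertical bars for 1 SE, horizontal bars for the target's extent and filled points for an adjusted p under 0.05. The 19 filled points on chromosome 7 lie between 1.78 and 3.21 and the 17 on chromosome 19 between 1.59 and 2.43, while neighbouring open points lie near 0, apart from 1 per span above 2. Most open points near 0 on chromosome 7 belong to targets that were dim in both groups.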

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

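Alternatives were chosen before the data were examined, apart from the count by locus and the batch term with an estimated correlation. Higher and lower targets numbered 399 and 141 with arrays centred on the reference genes (322 higher at least 2-fold), 163 and 206 in the authors' value table (160 higher at least 2-fold), 24 and 58 with 1 target per gene symbol (22 and 53 at least 2-fold), and 56 and 106 by locus with each target of no position counted by itself. With the array number range as a batch term limma called 0 and 0 (0 and 0 at least 2-fold), and the ordinary test per target called 0 and 0 (0 and 0 at least 2-fold), with 1586 higher and 1802 lower at an unadjusted p under 0.05 and a lowest adjusted p of 0.0728. A share of 0.05 of all targets would pass that unadjusted threshold with no difference. Without 1 array, higher targets numbered 34 to 67 and lower 59 to 120, the same at least 2-fold: 67 and 120 without control replicate 1, 56 and 89 without 2, 34 and 59 without 3, and 57 and 77, 67 and 98, and 43 and 76 without morpholino replicates 1 to 3, partly because fewer arrays entered. The replicate block gave 46 higher and 88 lower (46 and 88 at least 2-fold). Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at -0.013, -0.097 and 0.17, and 2 of the 6 arrays correlated best with their own number.

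The nanog difference changed sign to 0.105 with reference centring and 0.0084 with array weights, and ranged from -0.0412 to 0.021 without 1 array, above 0 without control replicate 2 (0.013) and without morpholino replicate 3 (0.021). Of the list tests, fry gave adjusted p = 0.00477 for early zygotic and ventral lists and 0.0169 for yolk syncytial layer and neuroectoderm. It gave 0.0359 for pluripotency and 0.00153 for stress, all in the direction of camera. With camera at an estimated correlation, early zygotic, ventral and stress lists had adjusted p = 0.133. Yolk syncytial layer had 0.173, neuroectoderm 0.273 and pluripotency 0.412, so none of the 15 lists given passed camera so. With the batch term as well, these were 0.654, and 0.659 for neuroectoderm, and Nodal signalling turned (0.929). Reference centring gave adjusted p = 0.0281 for endoderm and turned the direction of mesoderm (0.311) and the organizer (0.947). The batch term gave 0.00403 for the enveloping layer and turned Nodal signalling (0.924). Mesoderm also turned without the targets below the 25th percentile (0.981) and with fry (0.229), and maternal genes with array weights (0.948). Without 1 array, adjusted p ranged from 0.4 to 0.841 for mesoderm, 0.305 to 0.97 for the organizer, 0.0053 to 0.919 for the enveloping layer, 0.559 to 0.962 for maternal genes, 0.673 to 0.989 for Nodal signalling and 0.00308 to 0.057 for pluripotency. Directions that turned there were those of mesoderm (0.711) and the organizer (0.696) without control replicate 1 and without morpholino replicate 3 (0.841 and 0.97), the enveloping layer without control replicate 1 (0.59), maternal genes without control replicate 2 (0.889) and morpholino replicate 3 (0.563), and Nodal signalling without morpholino replicate 1 (0.989). The value of grip2a turned to 0.0114 with reference centring and 0.0895 with the batch term. The cause was not tested. Of the 35 named genes called, 34 passed in the value table, 35 with reference centring, 28 without background correction, 19 with the block and 13 without each array in turn. Probe values were not used here, so the mean of log2 probe values was not run. Signal near the lowest value of 5.66 limits the folds of dim targets.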

Other observations

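The families in this paragraph were chosen after their values were seen. All 4 measured members of the draculin group, zinc finger genes next to each other on Zv7 chromosome 5 between 45966113 and 46017077, fell. On the log2 scale drl fell by 2.29 (SE 0.18, adjusted p = 0.00496, limma), drll.1 fell by 2.14, drll.2 fell by 2.25 and drll.3 fell by 2.18, and each kept that direction and its call under the 3 scaling alternatives. The call of drll.3 was lost without control replicate 3 (adjusted p = 0.0649) and without morpholino replicate 3 (0.058), and similar copies can share probe signal. Of 12 measured hairy-related genes her5 and her11, neighbours on Zv7 chromosome 14, fell, and her11 fell by 2.90 (SE 0.21, adjusted p = 0.00362), while her3 rose and 9 did not pass. Of 11 measured frizzled genes, which encode Wnt receptors, fzd10 and fzd9b rose, fzd4 fell by 2.91 (SE 0.23, adjusted p = 0.00563) and 8 did not pass. Of 32 measured claudin genes 0 passed.

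Among the tests below, those of younger embryos and both of chance position were chosen only after the result was seen. Of the 10 splits of the 6 arrays into 3 and 3, 1, the real one, called 249 targets, and the highest other called 0. For the gene lists 1 of the 10, again the real one, called 6 of the 15 lists given, and the highest other called 4. With 10 splits no share under 0.05 can be reached. Every other split also mixes the groups on each side, so a difference between groups of any cause widens the spread there and lowers the calls.

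The fall of early zygotic genes was weighed against younger embryos in the morpholino group and against a difference between array number ranges. Embryos that were only younger should have zygotic patterning genes lower together, but of 111 genes on 7 patterning lists 5 were called higher (her3, foxa2, cdx4, lft1 and tbxta) and 19 lower. Some of these lists share members with the oocyte and maternal list, so not all 111 genes need be lower in younger embryos. Fewer of the 5 higher genes passed in some fits: 2 without background correction, 2 with the replicate block and 1 or 2 without each array in turn. Their calls were not kept with the array number range as a batch term. That fit rests on 1 morpholino array, and the log2 folds of the 5 ran from 1.46 to 3.82 in it. Over 15 settings the log2 folds of these 5 lay between 1.13 and 3.82. The 5 were picked on the same arrays, so folds above 0 there are no further support. Of the 5, only her3 passed without each array in turn. The calls argue against a uniform delay as the whole explanation only as far as they hold, and a partial delay stays open. A difference between ranges stays open: inside the shared range the list median was -0.499, with 19 of 27 members below 0, but that range holds 1 morpholino array, which is too few to exclude it. A loss of activation by the targeted factor may also account for the fall and was not tested separately, since no other morpholino or rescue was analysed here.

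The stress and interferon list was higher by camera and by fry (adjusted p = 0.00153 with fry), with 14 of its 17 members above 0. By itself 0 of the 17 passed. The camera call was lost with an estimated correlation (adjusted p = 0.133), as it was for early zygotic genes at the same value. The estimate was -0.0458 for the stress list, below the preset 0.01, and 0.189 for early zygotic genes. Correlation between its members therefore does not account for the loss of the stress list's call. A side effect of the morpholino was not tested apart from the loss of nanog, because 1 morpholino was arrayed, and stays open for all changes given here.

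The gathering of higher targets in a few loci was first seen in these data and then tested on them. Draws were run for higher targets only. The 147 placed lower targets lay in 103 loci, of which 4 held 5 or more called targets, so gathering may not be particular to higher targets. Of 95 placed higher targets 50 lay within 1 Mb of another, and 0 of 1000 random draws of as many targets had as many, with a highest draw of 26. With overlapping or same-named targets counted as 1 position, 31 of 80 lay so, 0 of 1000 draws had as many and the highest had 20, but the draws treat positions as independent, which targets that share signal are not, so they do not count separate transcripts. Cross-hybridisation between similar targets stays open: within-group deviations of targets in a span correlated at 0.636 on average over both spans (0.423 on chromosome 7 and 0.849 on chromosome 19), against 0.306 between targets of different spans and 0.0467 among the other higher targets, so part of it was not particular to a span, and shared regulation predicts such correlations too. A candidate explanation is that fewer transcripts than targets rose, which was not tested on probe sequences.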
